A study of Mus musculus with 32 samples.

How the data were processed

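Mouse FE1 lung epithelial cells were exposed to 0, 1, 4, 6 or 10 mM hydrazine for 4 h and collected at once or after a further 20 h without the compound. Per the labels, total RNA was extracted with Qiazol and treated with DNase, and poly-A selected, stranded libraries were made from 1 µg of RNA with 15 PCR cycles. Sequencing was paired, with reads of 75 bp on a NextSeq instrument. The deposited table held expected counts per gene for 32 libraries, which the authors had computed. The aligner, the quantifier settings and the genome build of the authors were not given in the sources used here.

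The groups held 3 libraries each, apart from 4 mM at 4 h, which held 5. Nothing in the labels stated that replicates were separate cultures, so the p-values measured the spread between these samples, which may be technical. All 32 libraries were kept. Totals ran from 10560889 to 17086663 counts per library. No 2 libraries were copies of each other: the chi-square per degree of freedom between replicates was at least 2.10.

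The table held 49585 entries, of which 28053 had a count in any library. Of all 49585 entries, 48398 carried Ensembl identifiers, and 48174 entries, or 97.2% of all, matched a symbol in GENCODE M21. Identifiers without a match held 0.0181% of the counts. The identifier version was the same as in that annotation for 87.8% of all entries. Gene locations were read from GENCODE M21 on GRCm38 by gene identifier, and the build used by the authors may differ. Expected counts were not all whole numbers (73.9% of the values above 0 were), and all were rounded before testing.

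The computation done here started from those counts. Genes were kept with the edgeR filter on expression (minimum count 10, minimum total 15), which left 13258 genes. Libraries were scaled with the trimmed mean of M-values (TMM). A single model with 1 coefficient per group was fitted to all 32 libraries with robust estimation, 22 residual degrees of freedom and a common biological coefficient of variation of 0.0847. Adjusted p-values for genes came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes of a comparison, and a gene was called at adjusted p < 0.05. Log2 fold changes are given with standard errors derived from the fold change and the F statistic, and CPM values as mean and SD over libraries. A prior count of 2 was used for log2 CPM values, as in the principal components and library means, and not for the fold changes of the test. Confidence intervals were not computed.

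The 14 comparisons were each dose against the vehicle of its own time, 10 mM against 4 mM at each time, and, for each dose, the effect after washout minus the effect at 4 h. Beside the genes of the lists, genes were named by rule: called and at least 5 CPM in 1 of the groups compared. They were taken by the size of the fold change in each direction. For comparisons with vehicle, every library of the treated group also had to lie on the same side of every vehicle library. For 10 against 4 mM and the differences between times, libraries were not required to separate. The 30 gene lists held known targets or members of pathways and were written from general knowledge. Lists were tested with camera on voom values, with a preset correlation of 0.01 between genes, and adjusted over 240 tests of lists and comparisons with vehicle. Camera was repeated with an estimated correlation, whose median was 0.127, and fry was run beside it. The lists, groups, comparisons, thresholds and most alternatives were chosen before the data were examined. The alternatives that leave out library c of 6 mM after washout or library a of 10 mM after washout were added later.

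The alternatives tried were the DESeq2 Wald test, DESeq2 size factors, no filter on low counts, no robust estimation, only the compared groups in the fit, only the same time point in the fit, a block for the replicate letter, each library left out in turn, only replicates a to c of 4 mM at 4 h, and both later omissions. Splits of the pooled libraries into groups of the same sizes gave counts under exchanged names. Alternatives that the design held for a table without counts were not applicable and were not run.

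The computation was tested on simulated data with known changes in 50 genes for each fold. For 10 mM at 4 h, edgeR recovered 39, 46, 49 and 49 genes at 1.5-, 2-, 3- and 4-fold, and called 9 unchanged genes among 12770. For 10 mM after washout it recovered 37, 45, 50 and 50 genes and called 14 unchanged genes among 12819. A list raised in the simulation reached 1.99e-166 and 6.09e-150 with camera, and an unchanged list 0.727 and 0.950.

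The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and blastn 2.17.0. Reads were not available here, so alignment, strand and read quality were not examined. Splicing, transcripts and variants were left out because the table held 1 value per gene.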

Results

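Hydrazine changed the RNA of FE1 cells at 4 h, with more genes called at each higher dose. Fewer genes were called 20 h after the compound was removed. Mdm2, which encodes the ubiquitin ligase that restrains p53, stood at 260 ± 14.2 CPM in the vehicle at 4 h and at 364 ± 22.1, 894 ± 34.3 and 1783 ± 85.0 CPM at 4, 6 and 10 mM. After washout of 10 mM it stood at 373 ± 7.92 CPM against 261 ± 7.23 CPM (n = 3 per group, 5 for 4 mM at 4 h). Ccnb1, the mitotic cyclin B1, fell from 270 ± 20.9 CPM to 85.6 ± 4.00 CPM at 4 mM, and Ddit3, a stress transcription factor, rose from 31.8 ± 8.96 to 212 ± 11 CPM at 10 mM. On principal components, which carried 27.7% and 14.1% of the variance, the libraries at 4 h spread by dose while the washout libraries of all doses lay beside the washout vehicle.

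**Figure D1:**
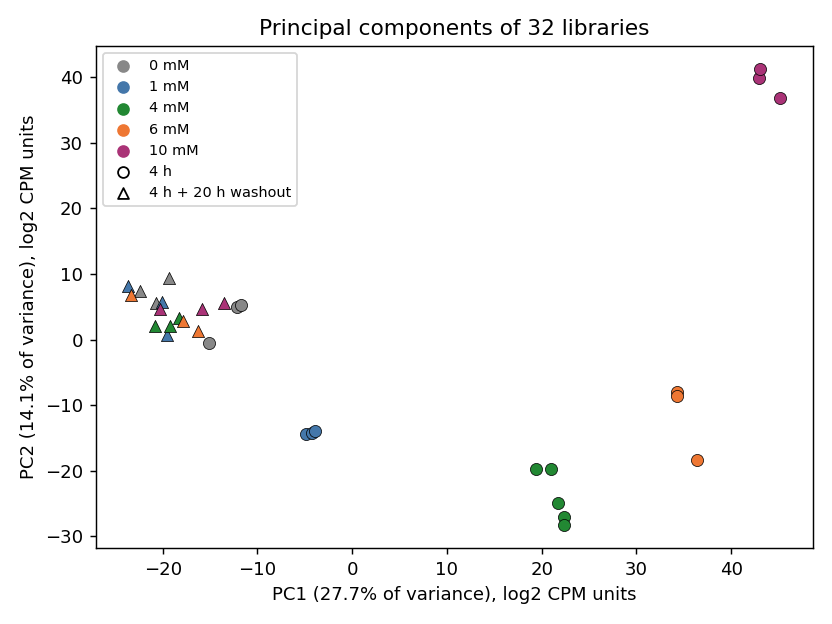
Each point is 1 of 32 libraries, on components 1 (27.7% of variance) and 2 (14.1%) in log2 CPM units, with colour for dose, circles for 4 h and triangles for 4 h plus 20 h washout. The 10 mM libraries at 4 h reached 42.9 to 45.1 on component 1, while all washout libraries lay between -23.6 and -13.5.

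At 4 h, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1305 genes at 1 mM (594 higher, 711 lower), 5113 at 4 mM (2585 higher, 2528 lower), 5281 at 6 mM (2686 higher, 2595 lower) and 6640 at 10 mM (3445 higher, 3195 lower). At least 2-fold were 48, 467, 519 and 597 higher and 23, 136, 267 and 697 lower. The 6640 genes at 10 mM were 50.1% of the genes tested, so the scaling, which takes most genes as unchanged, was itself less certain there. At 1, 4 and 6 mM the share was 9.84%, 38.6% and 39.8%. A list with calls in both directions thus need not differ from other genes. Scaling with DESeq2 size factors left all 4 counts within 1.5-fold, but it turned the balance to 2494 higher and 2629 lower at 4 mM and to 2594 and 2684 at 6 mM. The 1 mM count was the least stable: it was 2088 with only the compared groups in the fit, 1999 with only the same time point and 1997 without library c of 6 mM after washout. It was 703 and 669 without vehicle libraries a and c, and 819 and 731 without 1 mM libraries a and b.

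**Figure D2:**
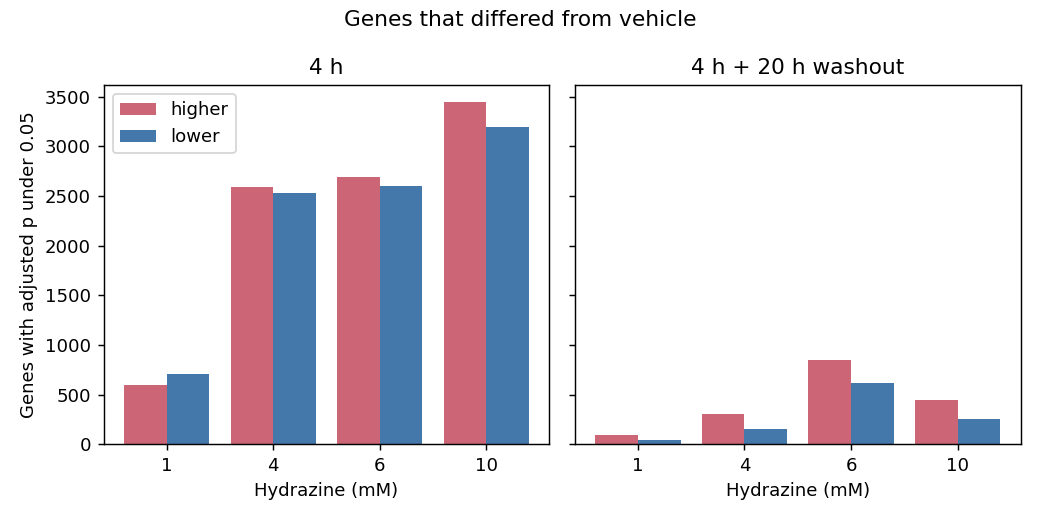
Bars give the number of genes called higher or lower than the vehicle of the same time at each dose, in 1 panel for 4 h and 1 for washout. At 10 mM the total was 6640 at 4 h and 705 after washout.

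Most genes of mitosis were lower at 4 h at all doses. Pif1, a DNA helicase gene outside the mitosis list, fell with a log2 fold change of -2.78 ± 0.08 at 4 mM (adjusted p = 1.67e-21, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), -3.77 ± 0.11 at 6 mM and -2.86 ± 0.10 at 10 mM. Plk1, a mitotic kinase, went from 160 ± 11.8 to 34.3 ± 1.57 CPM at 4 mM, and Aurka, another mitotic kinase, from 129 ± 10.2 to 24.9 ± 1.47 CPM at 6 mM (n = 3, 5 for 4 mM). Of 29 mitosis genes, 21 were lower at 1 mM, all 29 at 4 and 6 mM and 27 at 10 mM (24, 29, 29 and 27 when adjusted over the list alone). None was higher. The median log2 fold change was -0.37, -0.91, -1.08 and -0.51, lowest at 6 mM, but 6 mM was not tested against 4 mM. Ccnb1 fell by -1.66 ± 0.05, -1.69 ± 0.06 and -1.18 ± 0.06 from 4 to 10 mM, where 4 and 6 mM were alike within their standard errors. Camera gave adjusted p = 3.84e-26, 3.67e-38, 1.16e-35 and 7.63e-14 for the 4 doses, and adjusted p = 0.00249, 0.000432, 0.000547 and 0.0292 with an estimated correlation. Of 67 replication-linked histone genes only 6 passed the filter on low counts, so the family as a whole was not measured. The libraries were poly-A selected, so RNA of the family without a poly-A tail was not captured. The values of the 6 thus cover only RNA with such a tail. Of these 6, 3, 5, 4 and 3 were lower, with Hist1h2bc higher at 10 mM (1.27). Camera gave adjusted p = 0.000555 at 1 mM, 0.00911 at 4 mM and 0.0421 at 6 mM for the histones, and adjusted p = 0.0468, 0.130 and 0.273 with an estimated correlation. The 6 mM call also ended without library c of 6 mM after washout (0.206). At 10 mM the camera p was 0.670.

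Most known p53 targets were higher from 4 mM on. At 10 mM Mdm2 rose by 2.78 ± 0.06 log2 units (adjusted p = 4.08e-25, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Btg2, an antiproliferative gene, by 1.99 ± 0.10, Fas, a death receptor, by 1.51 ± 0.10, and Cdkn1a, the cell cycle inhibitor p21, from 131 ± 7.06 to 281 ± 4.47 CPM (n = 3). Gdf15, a stress cytokine gene kept in the ATF4 list, was close to 0 in the vehicle at 0.0856 ± 0.0859 CPM and reached 1.08 ± 0.15, 2.74 ± 0.16 and 5.48 ± 1.02 CPM at 4, 6 and 10 mM. Of 27 tested p53 targets, 6 were higher and 3 lower at 1 mM, 17 and 2 at 4 mM, and 23 and 0 at both 6 and 10 mM. When adjusted over the list alone, 7, 17, 24 and 23 were higher and 3, 2, 0 and 0 lower. Camera gave adjusted p = 0.236 at 1 mM and 1.69e-07, 1.85e-16 and 1.34e-12 at 4, 6 and 10 mM, and the last 3 held with adjusted p = 0.00249, 4.0e-05 and 0.000194 with an estimated correlation.

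Most targets of ATF4, the transcription factor of the integrated stress response, were higher over the same doses. Ddit3 rose by 1.64 ± 0.13, 2.23 ± 0.14 and 2.73 ± 0.15 log2 units at 4, 6 and 10 mM (adjusted p = 1.14e-14 at 10 mM, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Trib3, a pseudokinase gene, went from 46.1 ± 13.5 to 195 ± 4.94 CPM at 4 mM, and Slc3a2, an amino acid carrier subunit, rose by 1.23 ± 0.06 at 10 mM (n = 3, 5 for 4 mM). Of 38 ATF4 genes, 7, 35, 36 and 32 were higher at 1, 4, 6 and 10 mM (10, 35, 36 and 32 adjusted over the list alone), with 1 lower at 1 mM (2 alone) and 1 at 10 mM. Camera gave adjusted p = 0.00299, 6.37e-20, 9.06e-21 and 1.27e-11, and adjusted p = 0.545, 0.0353, 0.0319 and 0.124 with an estimated correlation. The 1 and 10 mM calls were thus lost with that setting. Genes of the endoplasmic reticulum branch of the unfolded protein response were mixed: 4 higher at 1 mM, 6 higher and 3 lower at 4 mM, 3 and 5 at 6 mM, and 7 and 6 at 10 mM, of 20, with the same numbers adjusted over the list alone. At 10 mM Herpud1 rose by 0.74 and Syvn1, its partner in protein degradation, fell by 0.98, while Hspa5, the main chaperone of the compartment, had a log2 fold change of 0.03 (adjusted p = 0.733 by edgeR's quasi-likelihood test). Camera called this list at 1 mM (adjusted p = 4.68e-05; adjusted p = 0.0901 with an estimated correlation), with p of at least 0.333 above 1 mM.

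**Figure D3:**
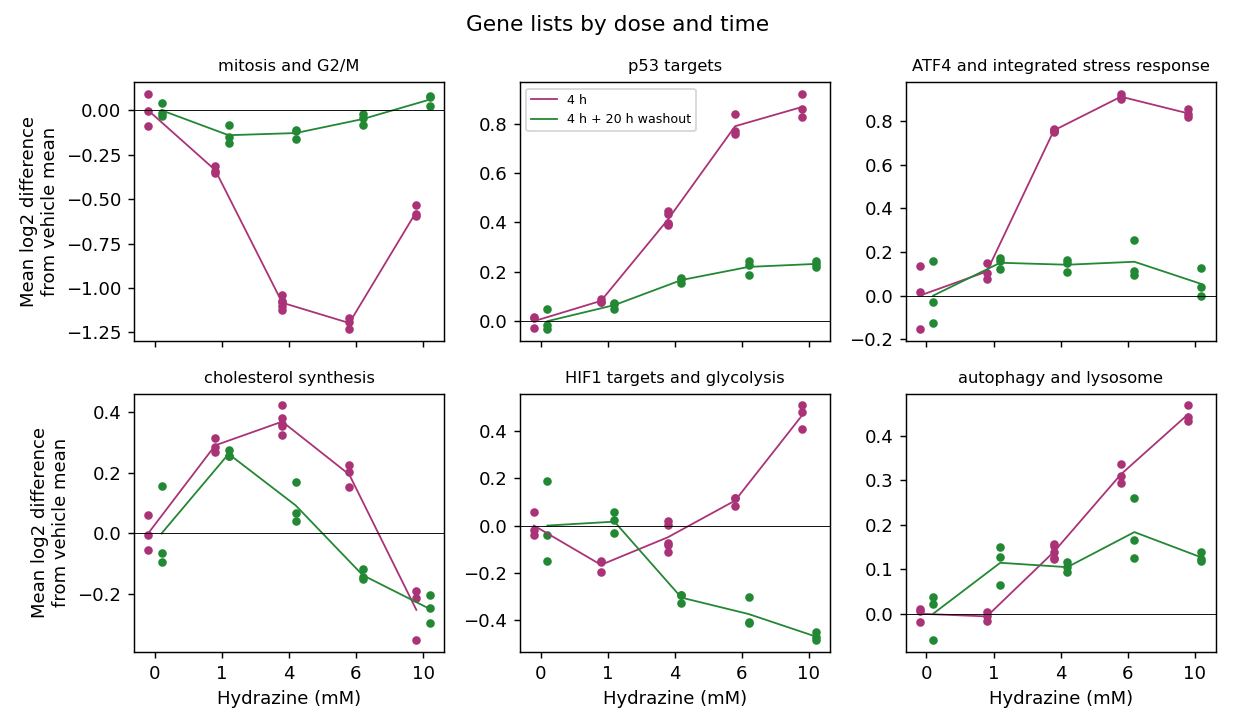
Points are libraries and lines group means of the mean log2 difference from the vehicle of the same time, against hydrazine dose (mM, evenly spaced), for 6 gene lists at 4 h and after washout. The median gene change of the mitosis list was -1.08 at 6 mM and 4 h, and that of HIF1 targets was -0.47 after washout of 10 mM.

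Genes of the NRF2 antioxidant pathway moved in both directions. At 10 mM Hmox1, which encodes heme oxygenase 1, rose from 128 ± 10.9 to 247 ± 3.26 CPM (log2 fold change 0.95 ± 0.06, adjusted p = 1.17e-13, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Txnrd1, the cytosolic thioredoxin reductase, fell from 444 ± 26.9 to 236 ± 13.2 CPM, Srxn1, which repairs peroxiredoxins, fell by 0.68 ± 0.05, and Osgin1, an oxidative stress gene, fell by 0.64 log2 units (n = 3). At 1 mM Hmox1 was lower at 69.6 ± 3.82 CPM. Of 28 NRF2 targets, 2, 10, 7 and 8 were higher and 3, 3, 3 and 13 lower at 1, 4, 6 and 10 mM (alone 3, 10, 7 and 8 higher and the same numbers lower). Camera did not call the list at any dose (adjusted p = 0.904, 0.257, 0.448 and 0.333). Of 19 glutathione genes, 2, 6, 7 and 5 were higher and 0, 3, 3 and 7 lower, with the same numbers adjusted over the list alone and camera adjusted p of at least 0.381. Gss, the last enzyme of glutathione synthesis, rose by 0.59 and Gclm, a subunit of the enzyme that limits it, fell by 0.30 at 10 mM. Slc7a11, the cystine carrier, rose by 0.65 ± 0.06 at 4 mM and fell by 0.46 log2 units at 10 mM.

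Some metal, heat shock and iron genes changed at 10 mM. Mt1, a metal-binding metallothionein, went from 53.9 ± 12.4 to 229 ± 34.4 CPM at 10 mM (log2 fold change 2.09 ± 0.21, adjusted p = 1.55e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Mt2 rose by 2.07 ± 0.25. Mtf1, the zinc sensor that drives both, fell by 0.67 log2 units. Of the 6 zinc genes, 3 were higher and 1 lower at 10 mM. Camera gave p = 0.354 there, while it called 1 mM (2 lower, adjusted p = 0.0273; adjusted p = 0.138 with an estimated correlation). Of 20 heat shock genes, 11 were higher and 3 lower at 10 mM (11 and 4 alone), among them Hspa8 (0.57) and Chordc1 (-0.50), and camera p was at least 0.112 at all doses of 4 h. Of 10 iron genes, 8 were higher at 10 mM, such as Ftl1, a ferritin chain, at 0.76 and Tfrc, the transferrin receptor, at 0.48 (camera adjusted p = 0.0337; adjusted p = 0.0976 with an estimated correlation).

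Most immediate early genes were lower at 1 mM and most were higher at 10 mM. Jun, a transcription factor, had a log2 fold change of -0.79 at 1 mM and 1.90 ± 0.12 at 10 mM, and Fos, its partner, reached 2.60 ± 0.36 at 10 mM (adjusted p = 5.4e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3). Dusp6, a phosphatase of the MAP kinase pathway, was lower at all doses, and Dusp1 rose by 2.31 ± 0.12 at 10 mM. Of 21 immediate early genes, 0, 3, 6 and 13 were higher and 14, 9, 6 and 4 lower at 1, 4, 6 and 10 mM (alone 0, 3, 6 and 13 higher and 17, 9, 6 and 4 lower). Camera called 1 mM (adjusted p = 2.04e-13) and 10 mM (adjusted p = 0.00229), neither of which held: adjusted p = 0.0542 and 0.459 with an estimated correlation. The 4 h vehicle varied for some of these genes and for Atf3, which was in the ATF4 list, with Atf3 at 14.2 ± 10.0 and Egr1 at 5.95 ± 3.17 CPM against 1.54 ± 0.21 and 1.62 CPM at 1 mM. The calls for Atf3 and Fosl1 at 1 mM ended with only the compared groups in the fit, and that for Egr1 ended without vehicle library a.

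At 10 mM most of the tested genes controlled by NF-kB were higher. Nfkbia, the inhibitor that NF-kB induces, went from 14.9 ± 1.20 to 77.9 ± 2.43 CPM at 10 mM (log2 fold change 2.39 ± 0.10, adjusted p = 3.87e-18, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Ccl2, a monocyte chemokine, rose by 2.01 ± 0.17. Csf1, the macrophage growth factor, fell by 1.52 ± 0.08 log2 units. Of 16 genes, 2, 7, 7 and 11 were higher and 3, 3, 1 and 2 lower (alone the same numbers higher and 4, 4, 1 and 2 lower). Camera called 6 mM (adjusted p = 0.0105; adjusted p = 0.338 with an estimated correlation) and 10 mM (adjusted p = 0.0011; adjusted p = 0.236 with an estimated correlation).

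Cholesterol genes were mostly higher at 1 and 4 mM and more were lower than higher at 10 mM, while fatty acid genes moved both ways there. Hmgcs1, an early enzyme of cholesterol synthesis, rose from 536 ± 20.2 to 710 ± 31 CPM at 1 mM (log2 fold change 0.41 ± 0.07, adjusted p = 0.000235, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3). At 10 mM its log2 fold change was -0.38 ± 0.07. Of 26 cholesterol genes, 14, 19, 12 and 3 were higher and 0, 1, 0 and 15 lower at 1, 4, 6 and 10 mM (alone 19, 21, 12 and 3 higher and 0, 1, 1 and 15 lower). For the list, camera gave adjusted p = 9.85e-14, 4.25e-08, 0.0143 and 0.00183, and adjusted p = 0.0465, 0.147, 0.546 and 0.444 with an estimated correlation, so only 1 mM held. Of 15 fatty acid genes, 8, 8, 5 and 6 were higher and 0, 1, 3 and 5 lower (alone 9, 10, 5 and 6 higher and 0, 2, 3 and 5 lower). Elovl6, an elongase, fell by 1.34 ± 0.09 and Fasn, the fatty acid synthase, by 0.89 ± 0.12 at 10 mM, while Acsl3 rose by 0.75. Camera called that list at 1 mM (adjusted p = 4.09e-09; adjusted p = 0.0249 with an estimated correlation) and at 4 mM (adjusted p = 0.0036; adjusted p = 0.261 with an estimated correlation).

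At 10 mM most autophagy and lysosome genes and most HIF1 targets were higher. Ctsb, a lysosomal protease, rose by 0.76 ± 0.05 (adjusted p = 3.25e-13, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Atp6v1a, a proton pump subunit, by 0.99 ± 0.08, and Sqstm1, the autophagy receptor p62, by 0.86 ± 0.07 log2 units at 10 mM (n = 3). Of 27 autophagy and lysosome genes, 0, 15, 17 and 20 were higher and 2, 3, 3 and 2 lower (alone 1, 16, 19 and 20 higher and 2, 4, 5 and 2 lower). By camera, adjusted p was 0.902, 0.00515, 2.21e-06 and 1.12e-07, of which 10 mM held (adjusted p = 0.0393 with an estimated correlation, against 0.310 and 0.0629 at 4 and 6 mM). Among targets of the hypoxia factor HIF1, Vegfa, an endothelial growth factor, rose by 1.16 ± 0.07 at 4 mM, and Bhlhe40, a transcription factor, by 2.38 ± 0.12 and Hk2, a hexokinase, by 2.13 ± 0.16 at 10 mM. Of 30 HIF1 targets, 0, 3, 7 and 19 were higher and 7, 6, 3 and 1 lower (alone 0, 3, 6 and 20 higher and 7, 6, 2 and 1 lower). Camera called 1 mM (adjusted p = 0.00355; adjusted p = 0.491 with an estimated correlation) and 10 mM (adjusted p = 1.85e-05; adjusted p = 0.310 with an estimated correlation).

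Recombination genes called at 1 and 4 mM were higher and most of those called at 10 mM were lower, while base excision repair genes moved both ways from 4 mM on. Exo1, a repair exonuclease, fell by 1.02 ± 0.08 at 10 mM (adjusted p = 3.33e-12, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Ccne2, the S-phase cyclin E2, by 1.84 ± 0.10, and Fen1, a flap nuclease, by 0.99 ± 0.08 log2 units, while Cdt1, a licensing factor, rose by 0.69. Of 23 homologous recombination and Fanconi genes, 6, 11, 2 and 2 were higher and 0, 0, 5 and 10 lower (alone 6, 13, 2 and 2 higher and the same numbers lower). Camera called 1, 4 and 10 mM (adjusted p = 2.1e-05, 0.0148 and 0.0240; adjusted p = 0.0976, 0.363 and 0.396 with an estimated correlation). Of 32 replication genes, 5, 10, 3 and 8 were higher and 1, 0, 6 and 11 lower (alone 10, 10, 3 and 8 higher and 1, 0, 5 and 11 lower), with camera calls at 1 and 4 mM (adjusted p = 1.32e-06 and 0.0270; adjusted p = 0.227 and 0.568 with an estimated correlation). Of 20 base excision repair genes, 1, 5, 4 and 7 were higher and 0, 4, 3 and 5 lower, and camera called none. Of all genes tested, 38.6%, 39.8% and 50.1% were called at 4, 6 and 10 mM, so calls in both directions were not particular to this list.

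Most cytosolic ribosomal protein genes were higher by small amounts at 10 mM. Of 84, 68 were higher and 1 lower (72 and 1 alone), with Rpl3 at 0.52 and Rpl12 at 0.48 and a median log2 fold change of 0.32. The camera test gave adjusted p = 2.61e-07 at 10 mM and 0.000495 at 6 mM (21 higher, 2 lower), and adjusted p = 0.665 and 0.799 with an estimated correlation. One-carbon genes had 10, 9 and 9 higher and 2, 3 and 4 lower at 4, 6 and 10 mM, of 23, with no camera call, and Mthfd2, a mitochondrial folate enzyme, at 0.82 at 10 mM. Mat2a, which makes S-adenosylmethionine, fell from 271 ± 3.34 to 46.0 ± 2.73 CPM at 10 mM (log2 fold change -2.56 ± 0.07, adjusted p = 4.31e-22, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 52 oxidative phosphorylation genes, 9 were higher and 4 lower at 10 mM, such as Sdha at 0.34 and Sdhd at -0.77, without a camera call at 4 h. Of 11 mitochondrially encoded genes, 4 were lower at 10 mM, with mt-Nd1 at -0.92 ± 0.07, and camera called none at 4 h. For mt-Atp6 the mean count was 9.4, against 59900.1 for Gm10925, a nuclear gene with the same sequence. Among 7 aryl hydrocarbon receptor targets, Tiparp rose by 1.59 ± 0.09 and Cyp1b1 fell by 0.98 ± 0.09 log2 units at 10 mM, again without a camera call at 4 h.

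Few epithelial, endothelial or leukocyte markers passed the filter on low counts. Of 16 epithelial markers 2 passed the filter, and Esrp2, an epithelial splicing factor, fell by 0.50 log2 units at 10 mM from 15.8 ± 0.97 CPM. Of 15 alveolar markers 8 were tested: Lpcat1, a surfactant lipid enzyme, fell by 1.30 ± 0.08 and Hopx by 0.86, and Pdpn rose by 0.48 at 10 mM, without a camera call at 4 h. Of 17 tested mesenchymal genes, 3, 9, 10 and 9 were higher and 0, 1, 1 and 4 lower, with Vim, an intermediate filament gene, at 0.49 and Col1a1, a collagen chain, at 5016 ± 470 CPM in the vehicle. Camera called 1, 4 and 6 mM (adjusted p = 0.00683, 0.0177 and 0.0255; adjusted p = 0.264, 0.328 and 0.339 with an estimated correlation). Of 12 endothelial and 14 leukocyte markers, 2 each were tested, and Flt1 (0.89) and Cd68 (0.78) were higher at 10 mM.

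Several genes outside the lists also had large changes. Celf5, an RNA-binding protein gene, stood at 1.97 ± 0.23 CPM in the 4 h vehicle, 6.76 ± 1.13 at 1 mM and 26.3 ± 3.31 at 4 mM, with a log2 fold change of 3.74 ± 0.17 at 4 mM (adjusted p = 8.94e-17, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Dact1, a Wnt pathway modulator, went from 1.60 ± 0.20 to 43.8 ± 2.59 CPM at 10 mM, Tppp, a tubulin binder, from 4.68 ± 1.31 to 51.2 ± 7.63, and Pim1, a kinase, from 8.26 ± 0.69 to 57.1 ± 4.42 CPM (n = 3). Fam180a rose by 3.19 ± 0.20, 4.00 ± 0.21 and 4.06 ± 0.21 log2 units at 4, 6 and 10 mM. Nectin4, an adhesion gene, was at 0.150 ± 0.14 CPM in the vehicle and 5.57 ± 0.32 at 10 mM, and Sec14l5 at 0.0906 ± 0.093 and 5.02 ± 1.66 CPM at 6 mM. On GRCm38, Mdm2 lay at 117688875 to 117710758 of chromosome 10, Celf5 at 81459227 to 81482709 of the same chromosome, and Ces2e at 104926260 to 104934672 of chromosome 8.

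The direct comparison of 10 with 4 mM at 4 h called 7203 genes (3628 higher and 3575 lower at 10 mM, with 333 and 864 at least 2-fold). The 4 mM group held 5 libraries, against 3 in the vehicle, so this count cannot be set directly against that of 10 mM against vehicle. With only replicates a to c of 4 mM it was 6385, and 4 mM against vehicle gave 4360 genes. Pim1 was higher at 10 mM by 2.92 ± 0.11 log2 units (adjusted p = 7.0e-19, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Tcim by 3.04 ± 0.21, from 3.62 ± 0.68 to 30 ± 5.82 CPM (n = 5 and 3). Per3, a clock gene, fell from 15.6 ± 1.45 to 2.28 ± 0.42 CPM. Between 4 and 6 mM, 1971 genes were higher at both doses and 2037 lower at both, with 8 in opposite directions. Independence gave 523.7 and 494.8. Between 4 and 10 mM, 1324 were higher and 1345 lower at both (671.7 and 609.2), with 578 opposite. Effects at 4 and 6 mM correlated with r = 0.816, and those at 4 and 10 mM with r = 0.469. The doses shared their vehicle libraries, and simulations with no effect but the same sharing gave r = 0.587 and 0.569. Since r depends on how widely effects spread, these values of r cannot be set directly against the real ones. The covariance of effects was 0.28 and 0.194, against 0.0485 and 0.046 in the simulations, which drew genes independently. The simulations gave no shared calls, but few calls arise without an effect, so this tells little.

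After washout fewer genes differed: 130 at 1 mM (92 higher, 38 lower), 461 at 4 mM (306 higher, 155 lower), 1466 at 6 mM (852 higher, 614 lower) and 705 at 10 mM (448 higher, 257 lower), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At least 2-fold were 5, 37, 99 and 71 higher and 2, 1, 14 and 11 lower. Ces2e, a carboxylesterase gene, was the clearest, at 6.62 ± 0.28 CPM in the vehicle and 23.0 ± 2.10, 43.7 ± 3.64 and 41.0 ± 2.16 CPM at 4, 6 and 10 mM (log2 fold change 2.63 ± 0.12 at 10 mM, adjusted p = 9.94e-16, n = 3). Celf5 remained higher by 1.47 ± 0.19, 1.86 ± 0.19 and 1.93 ± 0.19 log2 units, and its 6 mM call ended with only the compared groups in the fit. With only those groups the 4 counts were 0, 1429, 1 and 1399, and with only the washout libraries 1, 142, 492 and 372. Without library c of 6 mM they were 506, 975, 840 and 1208, and without the filter on low counts the first 3 were 82, 307 and 932. DESeq2 called 236 at 1 mM. Single libraries also moved these counts: 4 mM had 154 genes without vehicle c and 190, 219 and 277 without 4 mM a, b and c. At 6 mM there were 873, 894 and 732 without vehicles a, b and c and 2408 and 2660 without 6 mM a and b. At 10 mM there were 442 and 447 without vehicles b and c and 401 and 446 without 10 mM a and b.

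At 1 mM after washout, Mgp, a matrix protein gene, was higher by 1.66 ± 0.33 log2 units (adjusted p = 0.0121, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3), and Hmgcs1 stood at 438 ± 22.2 against 344 ± 45.4 CPM. Both calls ended without vehicle c (Mgp 1.29, Hmgcs1 0.26), without 1 mM b (1.59 and 0.32) and without 1 mM c (1.52 and 0.32). They also ended with only the compared groups in the fit, where 0 genes passed and 1508 were below 0.05 before adjustment, and the count was 1 with only the washout libraries. It was 50 and 5 without vehicles a and c and 196, 14 and 3 without 1 mM a, b and c, so a difference at 1 mM after washout was not established by gene.

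Many targets of HIF1 were lower after washout of 4 mM or more. Bnip3, a mitophagy receptor gene, stood at 28.8 ± 1.92 CPM at 10 mM against 78.1 ± 22.5 in the vehicle (log2 fold change -1.44 ± 0.14, adjusted p = 6.91e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ldha, the lactate dehydrogenase A gene, stood at 879 ± 17.1 against 1423 ± 140 CPM, Slc2a1, a glucose carrier, at 65.1 ± 4.28 against 106 ± 14.4 CPM, and Ak4, an adenylate kinase gene outside the list, fell by 0.78 ± 0.08, 0.94 ± 0.08 and 1.11 ± 0.08 log2 units at 4, 6 and 10 mM (n = 3). Of 30 targets, 0, 15, 18 and 20 were lower at 1, 4, 6 and 10 mM (0, 18, 23 and 22 adjusted over the list alone) and none higher, with medians of 0.01, -0.31, -0.36 and -0.47. For the list, camera gave adjusted p = 6.74e-18, 5.69e-16 and 2.72e-28 at 4, 6 and 10 mM, all of which held (adjusted p = 0.0281, 0.0353 and 0.00519 with an estimated correlation). In the washout vehicle 17 of the 30 targets were higher than in the 4 h vehicle. The calls for Ak4 and Bnip3 at 6 mM ended with only the compared groups in the fit.

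**Figure D4:**
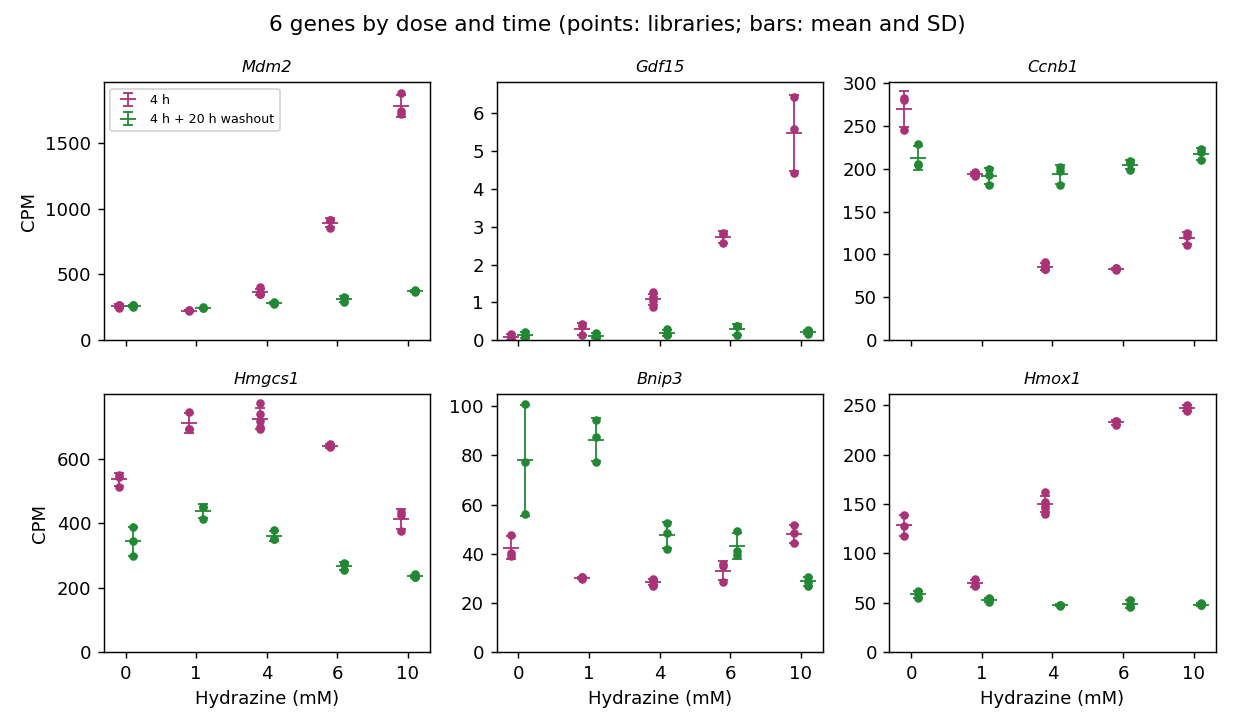
CPM of 6 genes against hydrazine dose (mM) at 4 h and after washout, with points for libraries and bars for mean and SD. Mdm2 reached 1783 CPM at 10 mM and 4 h and stood at 373 CPM after washout, while Bnip3 stood at 28.8 CPM after washout of 10 mM against 78.1 in the vehicle.

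Some responses outlasted the exposure. After washout of 10 mM, Mdm2 was higher by 0.51 ± 0.06 log2 units (adjusted p = 3.4e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Dcxr, a carbonyl reductase, by 1.18 ± 0.11 and Fas by 0.65, and of 27 p53 targets 1, 4, 10 and 9 were higher at the 4 doses and none lower (alone 4, 6, 12 and 10 higher and 2, 0, 1 and 0 lower). By camera, adjusted p was 4.37e-05, 2.19e-06 and 4.3e-08 at 4, 6 and 10 mM, and these held (adjusted p = 0.0178, 0.00519 and 0.00197 with an estimated correlation). Of 27 autophagy and lysosome genes 4, 6, 12 and 11 were higher and 0, 1, 1 and 1 lower (alone 6, 12, 15 and 14 higher and the same numbers lower), with Ctsd, a lysosomal protease, at 0.48 at 10 mM. The camera test gave adjusted p = 8.07e-07, 2.47e-06, 1.14e-09 and 4.98e-09, and adjusted p = 0.0542, 0.0635, 0.0249 and 0.0281 with an estimated correlation. In both lists the gene calls after 1 mM came from the comparison whose gene calls were not established. Abca1, a cholesterol exporter, stood at 10.6 ± 0.57 against 3.13 ± 0.50 CPM at 10 mM.

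Some cholesterol genes were lower after washout of 10 mM. Hmgcs1 stood at 236 ± 5.19 CPM after 10 mM against 344 ± 45.4 CPM (log2 fold change -0.54 ± 0.07, adjusted p = 4.08e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Fdft1, the squalene synthase, fell by 0.40 log2 units (n = 3). Of 26, 9 and 12 were lower after 6 and 10 mM (10 and 17 alone) and none was called after 4 mM. The 6 calls after 1 mM (17 alone), all higher, came from the comparison whose gene calls were not established. For the list, camera gave adjusted p = 8.04e-18, 0.0429, 0.000204 and 2.06e-14, and adjusted p = 0.0269, 0.638, 0.340 and 0.0393 with an estimated correlation. Fatty acid genes had 2 higher after 1 mM and 1 lower after 6 and after 10 mM, with camera calls at 1 mM (adjusted p = 3.21e-05; adjusted p = 0.0901 with an estimated correlation) and 10 mM (adjusted p = 0.0362; adjusted p = 0.407 with an estimated correlation).

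Few mitosis genes were called after washout, while some replication genes were lower after 4 mM or more. Ccnb1 had a log2 fold change of 0.03 after 10 mM (adjusted p = 0.854, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and of 29 mitosis genes 0, 2, 1 and 0 were lower and 0, 0, 0 and 1 higher (10, 6, 0 and 0 lower adjusted over the list alone). Camera still gave adjusted p = 3.37e-10, 7.12e-08 and 0.0395 at 1, 4 and 10 mM, none of which held (adjusted p = 0.0621, 0.108 and 0.565 with an estimated correlation). Replication genes had 6, 4, 7 and 4 lower of 32 (18, 19, 11 and 8 alone), where the 6 at 1 mM were not established by gene, with Mcm3, a helicase subunit, at -0.21 after 10 mM, a call that ended without vehicle c (-0.18), without 10 mM a (-0.18), with only the washout libraries and without the filter on low counts. By camera, adjusted p was 2.38e-16, 9.68e-16, 0.00052 and 0.000125 for replication, of which 1 and 4 mM held (adjusted p = 0.0281, 0.0294, 0.372 and 0.333 with an estimated correlation). Recombination genes had 1, 1, 0 and 0 lower, with camera calls at 1 and 4 mM (adjusted p = 1.25e-05 and 0.00101; adjusted p = 0.0901 and 0.236 with an estimated correlation). Base excision repair had 1, 1, 3 and 2 lower, with camera calls at 4 and 10 mM (adjusted p = 0.0272 and 0.0374, or 0.323 and 0.338 with an estimated correlation). None of the 6 tested histone genes was called.

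Few stress genes were called after washout. Ddit3 had a log2 fold change of -0.06 after 10 mM (adjusted p = 0.906, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Gdf15 stood at 0.223 ± 0.05 against 0.129 ± 0.0795 CPM. Of 38 ATF4 genes 0, 1, 6 and 0 were higher (3, 1, 7 and 0 alone), with camera calls at 1, 4 and 6 mM (adjusted p = 4.46e-07, 6.11e-05 and 0.000261; adjusted p = 0.289, 0.389 and 0.444 with an estimated correlation). NRF2 targets had 2, 3, 5 and 2 higher and 0, 2, 5 and 3 lower, with a camera call at 1 mM (adjusted p = 0.0429; adjusted p = 0.376 with an estimated correlation), Nqo1, a quinone reductase gene, at 0.66 ± 0.14 and Hmox1 at -0.28 ± 0.07 after 10 mM. Those calls ended without 10 mM c (Nqo1, 0.48) and without vehicle b (Hmox1, -0.25). Glutathione genes had 1, 2, 5 and 0 higher, with camera calls at 1 and 6 mM (adjusted p = 0.00594 and 0.00683; adjusted p = 0.228 and 0.236 with an estimated correlation), and the 6 mM call ended without its library c (0.0722). Unfolded protein genes had 2 lower at 4 and at 6 mM (camera adjusted p = 0.000333 and 0.0322; adjusted p = 0.134 and 0.376 with an estimated correlation), and heat shock genes 5 lower at 4 mM (camera adjusted p = 8.46e-06; adjusted p = 0.257 with an estimated correlation). Immediate early genes had 2 higher at 10 mM, Dusp1 among them at 0.62 (camera adjusted p = 0.0429; adjusted p = 0.641 with an estimated correlation, and 0.0565 without library c of 6 mM), and NF-kB genes 2 lower at 6 mM and 1 at 10 mM, without a camera call. Zinc genes had 1 change at 6 and at 10 mM, and iron genes 2, 2 and 1 lower from 4 to 10 mM, with Tfrc at -0.55 ± 0.07 at 4 mM (camera adjusted p = 0.0167; adjusted p = 0.0629 with an estimated correlation).

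Ribosomal genes had most calls by gene among the remaining lists after washout. Ribosomal protein genes had 20 higher of 84 at 6 mM (67 alone), with camera adjusted p = 6.13e-16 and adjusted p = 0.459 with an estimated correlation. Oxidative phosphorylation genes had 7 higher of 52 there (20 alone; camera adjusted p = 1.56e-07, adjusted p = 0.546 with an estimated correlation). Without library c of 6 mM, 1 ribosomal gene was higher (camera adjusted p = 0.0236), and the oxidative phosphorylation call ended (0.714). Mitochondrially encoded genes had no call by gene after any dose (camera adjusted p = 0.0011 at 1 mM; adjusted p = 0.236 with an estimated correlation). Aryl hydrocarbon receptor targets had 2 higher at 6 mM and 1 at 10 mM (camera adjusted p = 0.0106; adjusted p = 0.0862 with an estimated correlation). Mesenchymal genes had 1 and 2 higher at 4 and 6 mM, and one-carbon genes at most 3 lower. Of 27 interferon genes 2 were higher at 10 mM, Ifit2 at 0.47 and Tap1 at 0.71, with a list median of 1.56 (camera adjusted p = 1.85e-05; adjusted p = 0.565 with an estimated correlation). Both gene calls ended without library a of 10 mM (Ifit2 0.26, Tap1 0.34), and that of Tap1 also without vehicle b (0.71) or c (0.62). In library means the list median was 1.000 with all libraries and 0.118 without that library. At 1 mM camera also called the ribosomal (adjusted p = 4.2e-11; adjusted p = 0.546 with an estimated correlation), oxidative phosphorylation (2.31e-05; 0.650), mesenchymal (0.0246; 0.338), one-carbon (0.0285; 0.0976) and heat shock lists (0.0490; 0.638). At 4 mM it called the ribosomal (0.0428; 0.881), mesenchymal (0.0038; 0.236) and interferon lists (0.0428; 0.816), the last of which ended without library c of 6 mM (0.0504). Over all 240 list tests camera called 93, of which 25 held with an estimated correlation, and fry called 114.

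After washout, 10 mM differed from 4 mM in 137 genes (68 higher, 69 lower). Ces2e was higher by 0.84 ± 0.10 log2 units (adjusted p = 1.38e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3), Serpinb9b, a protease inhibitor gene, by 0.75 ± 0.14 (a call that ended without 4 mM a, at 0.57, and with only the washout libraries), and Il33, an alarmin cytokine gene, fell from 170 ± 12.1 to 88.6 ± 9.97 CPM. The count was 219 with DESeq2, 900 with only the compared groups in the fit, 22 with only the washout libraries and 375 without library c of 6 mM. It was 33 and 40 without 4 mM a and b, and 90, 46 and 55 without 10 mM a, b and c. Between 6 and 10 mM after washout, 305 genes were higher and 136 lower at both, and none changed in opposite directions. These effects correlated with r = 0.580 and had a covariance of 0.106. Simulations with no effect and the same shared vehicle libraries gave r = 0.508, a covariance of 0.0433 and no shared calls. As at 4 h, these values of r cannot be set directly against each other, and the lack of shared calls tells little. Between 1 and 4 mM after washout the covariance was 0.0775 against 0.0418 simulated, although 1 mM was not established by gene. A covariance above the simulated one thus does not by itself show a shared effect. At 10 mM, 242 genes were higher at 4 h and after washout and 99 lower at both, where independence gave 116.4 and 61.9, with 113 in opposite directions. The effects at both times correlated with r = 0.163.

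The effect of 10 mM after washout minus that at 4 h was tested directly. Dact1 differed by -5.28 ± 0.34 log2 units (adjusted p = 8.2e-13, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Gdf15 by -5.08 ± 0.93 (adjusted p = 0.000131 by the same test of edgeR with Benjamini-Hochberg adjustment). For Pif1, which fell at 4 h, the difference was 2.57 ± 0.12 at 4 mM and 3.62 ± 0.14 at 6 mM, and Aurka differed by 2.43 ± 0.11 at 6 mM. The counts were 2289 genes at 4 mM (1252 higher, 1037 lower), 3240 at 6 mM (1627 higher, 1613 lower) and 4830 at 10 mM (2393 higher, 2437 lower), and the 6 mM count was 1819 with only the compared groups in the fit.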

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

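The tests of the library of 6 mM after washout and of the vehicle cells at both times, and those of the interferon and mitochondrial genes, were chosen after the result was seen, as was the left-out library test of HIF1 targets.

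Dose effects differed between 4 h and washout by a test of the difference itself, the interaction term of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The effect after washout minus that at 4 h was past the threshold for 145 genes at 1 mM, 2289 at 4 mM, 3240 at 6 mM and 4830 at 10 mM. Collection time and handling were the same variable here, so the difference may belong to either. At 10 mM, 1 of 60 drawn splits of the libraries gave as many genes (5753 with only the compared groups in the fit, 5054 at most in another split). At 4 mM it was also 1 of 60 (3224 against 2), where 0 of the other drawn splits kept the 4 h groups whole, against 4 at each other dose. At 6 mM 3 of 60 splits gave as many (1819 against 2226) and at 1 mM 4 of 60 (148 against 660). Exchanging names within a time removes the dose effect there instead of making it equal at both times. These splits thus cannot decide whether chance gave the differences at any dose. The splits as large as the real one at 1 and 6 mM, and the 5054 genes at 10 mM, came from splits that kept the 4 h libraries in their real groups and mixed those of washout, so they held the real effect at 4 h. Splits that mixed the 4 h groups gave at most 2 genes at any dose.

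The 1 mM difference was unstable by count: 254 genes with DESeq2, 82 without the filter on low counts and 497 without library c of 6 mM after washout. At 4 h, it was 53, 240 and 69 without vehicles a, b and c, and 66, 70 and 83 without 1 mM libraries a, b and c. For washout libraries it was 85, 90 and 85 without vehicles a, b and c, and 54 without 1 mM b. The genes named for 1 mM were Atf3 (2.814), Egr1 (2.246) and Hist3h2a (1.587), whose effects were higher after washout, and Tppp (-1.469), Tbc1d8 (-1.02) and Dna2 (-0.971), whose effects were lower. The call of Atf3 ended in 11 of 12 fits with a library left out (2.271 to 3.028), all but that without 4 h vehicle b, and the call of Egr1 in 8 of 12 (1.726 to 2.442). For Egr1 these were the fits without 4 h vehicle a, any 4 h library of 1 mM, washout vehicles b and c and washout 1 mM b and c. The call of Tbc1d8 ended without washout vehicle a (-0.857).

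At 4 mM the differences in log2 effect were 2.57 for Pif1, 2.523 for Egr1 and 2.375 for Hist3h2a, genes that were lower at 4 h, and -2.812 for Tppp, -2.271 for Celf5 and -2.193 for Dact1, which were higher at 4 h. At 6 mM they were 3.615 for Pif1, 2.623 for Egr1, 2.425 for Aurka, -3.566 for Dact1, -3.449 for Tppp and -2.761 for Kif21b, a kinesin gene. At 10 mM they were -5.281 for Dact1, -5.076 for Gdf15 and -3.659 for Nectin4, whose call ended without washout vehicle b (-2.381). Pagr1a differed by 6.543 at 10 mM, but its values fell to near 0 in single libraries of other groups, such as 0.174 CPM in 4 mM c at 4 h against 14.8 CPM or more in the other replicates, so its counting was uncertain. Ddx60 (4.151) and Irgm2 (3.594), both induced by interferon, stood at 21.2 and 75.5 CPM in library a of 10 mM after washout, against at most 2.81 and 14.3 CPM in its replicates. Both calls ended without that library (1.84 and 1.736), without 4 h vehicle b (3.414 and 2.318), without any 1 of the 3 libraries of 10 mM at 4 h (4.066 at least for Ddx60, 3.552 at least for Irgm2), and without washout vehicle b (4.229 and 3.572) or c (3.783 and 3.168).

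A single sample stood far from the others of its group: in the 5 libraries of 4 mM at 4 h, Egr1 was at 0.608 CPM in library c, with a gap to the nearest library of 0.931 of the range of the group. The critical value is 0.71. Of 41 genes checked this was the only one, and about 1 in 20 passes by chance.

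Library c of 6 mM after washout stood apart from its replicates. Its deviation from the group followed transcript length with a rank correlation of -0.575, against -0.461 to 0.378 in libraries of other groups. The lowest of those, -0.461, was library b of 1 mM after washout. The other replicates stood at 0.459 and 0.504, but each was set against a mean that held library c, so they are not independent of it. Low depth was argued against by its rank of 21 among 32 totals, and a library of another dose by its place of 0.734 between vehicle and 10 mM, where its replicates stood at 0.802 and 0.811. The length trend stayed open as a candidate explanation, and no biological explanation was tested.

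HIF1 targets lay lower after washout of 10 mM, with a median log2 fold change of -0.47. A length trend was argued against, since the median was -0.462 after its removal, and so was a single library, since the median nearest to 0 was -0.400, without vehicle b. In the washout vehicle 17 of 30 targets were higher than in the 4 h vehicle and 1 lower, and in the washout cells of 10 mM 5 were higher and 11 lower than in the 4 h vehicle. Against the 4 h vehicle the list median was 0.3 in the washout vehicle and -0.163 in the washout cells of 10 mM. The comparison after washout used the vehicle of the same time, so the rise in vehicle cells is part of its baseline. The difference thus held a rise in the vehicle that the 10 mM cells did not show, and its cause was not tested.

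Mitochondrially encoded genes were split between entries. Of the 10 most abundant genes without a common name, 5 matched a mitochondrial transcript: Gm10925 matched mt-Atp6, Gm28661 mt-Co2 and Gm28437 mt-Co3 over their whole sequence at 100% identity, Gm29216 mt-Co1 at 99.8% and Gm28439 mt-Nd4 at 100%. The mean count of mt-Atp6 was 9.4 against 59900.1 for Gm10925, so reads may have been assigned to the nuclear copies, and values of these mitochondrial genes are not measures of their RNA. No biological explanation was tested.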

How the results depend on the processing

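The alternatives without library c of 6 mM or library a of 10 mM after washout and the tests on them were chosen after the data were seen, and the other alternatives were chosen earlier. No named gene or list reversed under the alternatives run. The balance of higher and lower genes did turn where it was near even: 4 mM at 4 h gave 2494 higher and 2629 lower with DESeq2 size factors and 6 mM 2594 and 2684, and 10 mM gave 3528 and 3772 with only the same time point. Of all 1466 genes called after washout of 6 mM, 617 stayed called without its library c, and the fold change of 1 changed sign. DESeq2 size factors, no robust estimation, the replicate block, replicates a to c of 4 mM at 4 h and the omission of library a of 10 mM after washout left all the counts they gave within 1.5-fold. For the counts below, the cause was not tested.

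With DESeq2, washout of 1 mM gave 236 genes (142 higher, 94 lower), 10 against 4 mM after washout 219 and the 1 mM difference between times 254, and washout of 4 mM gave 605 (319 higher, 286 lower). Without the filter on low counts, washout of 1, 4 and 6 mM gave 82, 307 (260 and 47) and 932 (667 and 265), and the 1 mM difference 82. With only the compared groups in the fit, 1 mM at 4 h gave 2088, washout of 1, 4, 6 and 10 mM 0, 1429 (759 and 670), 1 and 1399, 10 against 4 mM after washout 900 and the 6 mM difference 1819. With only the same time point, these were 1999 for 1 mM at 4 h, 1, 142 (119 and 23), 492 (369 higher) and 372 for washout, and 22 for 10 against 4 mM. Without library c of 6 mM after washout, 1 mM at 4 h gave 1997, washout of 1, 4 and 10 mM 506 (261 and 245), 975 (519 and 456) and 1208, 10 against 4 mM 375 and the 1 mM difference 497. With each library left out, counts ran from 669 to 1386 for 1 mM, 4184 to 5001 for 4 mM, 4583 to 4764 for 6 mM and 5877 to 6075 for 10 mM at 4 h. After washout they ran from 3 to 196, 154 to 361, 732 to 2660 and 401 to 631. For 10 against 4 mM they ran from 6190 to 7011 at 4 h and 33 to 92 after washout, and for the differences between times from 53 to 240, 1827 to 2246, 2677 to 3502 and 4346 to 4461.

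Of the calls for named genes, 0 were lost and 8 gained with DESeq2, 0 lost with its size factors, 28 without the filter, 48 with only the compared groups and 42 with only the same time point. DESeq2 gave no adjusted p for Gdf15 and Hspa1a after washout of 1 mM. With libraries left out in turn, 210 of the repeated gene calls were lost and 13 were gained. The other 2755 results were unchanged, which includes genes that were called in neither fit. The letters of the replicates were not taken to pair the samples, since 1 of 30 correlations of libraries that share a letter was over 0.1 at 4 h (median 0.023, against -0.0135 for different letters) and 3 of 30 after washout (median -0.012 against 0.016). At 4 h 9 of 15 libraries correlated best with their own letter, and after washout 5 of 15. Deviations at 4 h followed transcript length with rank correlations of 0.036 to 0.226 in libraries b and -0.223 to 0.006 in libraries a. In libraries c they were -0.065 to 0.101. A weak link by letter at 4 h was thus not excluded. With a block for the letter, 15 of the gene calls and 1 list call, interferon after washout of 4 mM (camera adjusted p = 0.0986), were lost. Of the 93 list calls by camera, 25 held with an estimated correlation and 68 were lost. With fry 18 were lost and 39 were gained. Of all 240 list results, 172 and 183 were unchanged, which includes lists that were called in neither test.

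With splits of the compared libraries, only the real one gave as many genes for 4 mM at 4 h (1 of 56 splits, 5806 genes against 2 at most in another). The same held for 10 against 4 mM at 4 h (1 of 56, 7797 against 1). These values argued against chance among these libraries but did not exclude it. A share of 1 of 56 is the lowest that such splits can give, and the replicates may be technical. The 10 splits of 3 against 3 libraries cannot give a share under 0.05: real and highest other counts were 2088 and 0 for 1 mM, 5560 and 2 for 6 mM and 6907 and 0 for 10 mM at 4 h, 0 and 16, 1429 and 2, 1 and 0, and 1399 and 1 for washout of 1 to 10 mM, and 900 and 2 for 10 against 4 mM after washout. As many genes came from 10 of the splits for washout of 1 mM and from 1 for the others. At totals of 10560889 to 17086663 counts, the minimum count of 10 limited which genes were tested.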

Other observations

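The tests of the interferon genes and of vehicle cells between the times were chosen after the result was seen.

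Some single genes gave steep responses. Ces2e, a carboxylesterase of the endoplasmic reticulum, stood after washout at 6.62 ± 0.28 CPM in the vehicle and 41.0 ± 2.16 CPM at 10 mM, and it was also called for 10 against 4 mM (log2 fold change 0.84 ± 0.10). Serpinb9b, a granzyme inhibitor, was higher by 1.59 ± 0.15 and Abca1, a lipid exporter, by 1.75 ± 0.21 log2 units after 10 mM, and Lbp, which binds bacterial lipopolysaccharide, by 1.68 ± 0.31 after 4 mM (n = 3). Mat2a, which makes the methyl donor of the cell, stood at 271 ± 3.34 CPM in the vehicle at 4 h and at 46.0 ± 2.73 CPM at 10 mM, and Ahrr, the repressor of the aryl hydrocarbon receptor, rose by 2.56 log2 units there.

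The dose order was not the same for all genes at 4 h. Per3, a clock gene, was at 15.6 ± 1.45 CPM at 4 mM and 2.28 ± 0.42 CPM at 10 mM, and Plk1 fell by 2.22 ± 0.06 log2 units at 4 mM and by 0.83 ± 0.07 at 10 mM. Between 4 and 10 mM, 578 genes were called in opposite directions. Between 1 and 10 mM 339 were, beside 239 higher at both and 316 lower at both.

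Interferon genes after washout of 10 mM rested on library a. The list median was 1.000 in library means of all replicates and 0.118 without that library, so a difference of that library alone is a candidate explanation. Without vehicle c the list median was 0.485.

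The vehicle cells themselves differed between times, with 913 genes called between the washout and the 4 h vehicle. Chemokine Cxcl1 had at most 5 counts in any library and was not tested.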
